A study of Mus musculus with 12 samples.

How the data were processed

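The gene counts were made by the authors before they were deposited. By the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6, aligned to the mouse genome (GRCm38/mm10) with STAR 2.7.6a and counted per gene with featureCounts. Per the labels, RNA was isolated with the RNeasy Plus Micro kit and libraries were made with the NEB Ultra II Directional kit. Aligner settings, the annotation release and the strand setting are not given in the sources used here. Even counts made up 67.1 to 75.9% of the nonzero values and counts of 2 outnumbered counts of 1 by 4.12 to 6.21 times, so both mates of a read pair appear to have been counted.

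All 12 value columns were used. Of 55471 genes 55230 were matched by identifier to GENCODE M21 on GRCm38, 54937 of them with identical coordinates. The 241 unmatched genes held 0.0044% of the counts. Column names carry S tags, and the columns named control were read as WT. The titles say KO whereas the genotype field says knockdown, and the titles' names are used here.

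Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at a minimum count of 10, which left 17063, and libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 12 libraries (6 residual degrees of freedom, edgeR's default prior count), and 9 comparisons were tested. A prior count of 2 was used only for log CPM values, as in the principal components. A call means an adjusted p (Benjamini-Hochberg) under 0.05. SE is the absolute log2 change divided by the square root of its F value. It measures spread between libraries, whereas the floor of 3 counts used for groups without counts covers counting error only. Both mates appear to have been counted, so 3 counts hold fewer than 3 fragments. Folds given as at least a value are therefore ratios to that floor and may overstate the true lower bound. Gene lists, 41 of them, were fixed before the data were examined and tested with limma 3.58.1 camera at a preset correlation of 0.01, with p-values adjusted over 369 tests. No list was called when the correlation between genes was estimated instead.

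Genes were named by a rule. They had to be protein coding, carry a given symbol, be called, have a mean of at least 2 CPM over the libraries compared and separate every library of the groups, and the largest changes were taken: 12 per direction for dKO and Prmt1_KO, 8 for the single knockouts and 5 elsewhere. Separation was not asked for departure from additivity or for the difference between dKO and Prmt1_KO. Up to 4 list members with the smallest p were named per list, and Hoxa9, Ctnnb1 and Prmt1 always. Some genes that met the rule are not reported here.

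Each comparison was repeated with RLE size factors, library-size scaling, scaling without mitochondrial and haemoglobin genes, no filter, a filter at a mean of 5 CPM, fits of only the groups compared or only the experiment, DESeq2 1.42.0, limma-voom with quality weights, and by leaving out each library in turn. Other tools were data.table (version 1.17.8), blastn 2.17.0, Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

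The analysis was first run on simulated counts with known changes in 16115 genes. At a log2 change of 1 it recovered 53.0% of changed genes for dKO against WT, 54.0% against Hoxa9_KO, 52.0% against Bcat_KO, 49.0% for Prmt1_KO, 27.0% for departure from additivity and 27.5% for the difference between dKO and Prmt1_KO. At a log2 change of 2 these were 82.0%, 84.0%, 85.0%, 81.0%, 72.0% and 73.5%. Calls among unchanged genes were 5, 8, 12, 5, 9 and 5 in the same order, 0 for each single knockout and 1 between the WT groups. A simulated list of 50 genes shifted by 0.5 was called by camera and 3 unshifted lists were not. Genes were simulated independently, so this could not show false calls of lists that come from correlation between genes.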

Results

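RNA was measured in LSK cells, the lineage-negative, Sca1-positive, Kit-positive population that holds the blood-forming stem cells and early progenitors. The cells came from primary transplanted mice 6 weeks after tamoxifen. The 12 libraries formed 6 groups of 2. WT, Hoxa9_KO, Bcat_KO (β-catenin, gene Ctnnb1) and dKO (both genes) made up 1 experiment, and WT_Prmt1 and Prmt1_KO the other. The series title links β-catenin and Hoxa9 to DNA replication, genome stability and stem cell function, and names the arginine methyltransferase Prmt1 as a factor they depend on. Library depth, to 5 digits, was 18893000 and 21235000 counts in WT, 17570000 and 24163000 in Hoxa9_KO, 29944000 and 40554000 in Bcat_KO, and 26755000 and 25651000 in dKO. It was 17592000 and 22039000 in WT_Prmt1 and 17951000 and 24414000 in Prmt1_KO. Libraries are named by their group and their S tag. Values below are log2 fold changes ± SE over 2 libraries per group unless another unit is given, and every gene named for a large change between 2 groups had all libraries of one group beyond all libraries of the other. Whether the libraries of a group came from separate animals is not given in the sources used here, so the p-values may measure technical spread only.

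Hoxa9 mRNA was low in both groups in which Hoxa9 was targeted. Hoxa9 (ENSMUSG00000038227, GRCm38 chromosome 6, 52223100 to 52231089, minus strand), a homeobox transcription factor, stood at 58.7 and 59.9 CPM in WT, 12.2 and 8.36 in Hoxa9_KO, 49.2 and 61.9 in Bcat_KO, 9.21 and 8.92 in dKO, 44.7 and 44.4 in WT_Prmt1, and 41.1 and 43.0 in Prmt1_KO. It fell by 2.53 ± 0.17 in Hoxa9_KO (adjusted p = 4.99e-08) and by 2.71 ± 0.17 in dKO (1.25e-08). Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, plus strand), which encodes β-catenin, was at 315 and 342 CPM in WT, 363 and 349 in Hoxa9_KO, 276 and 267 in Bcat_KO, and 227 and 235 in dKO. It fell by 0.28 ± 0.07 in Bcat_KO (0.0170) and by 0.51 ± 0.07 in dKO (0.000109). The call in Bcat_KO was lost without WT S2 (0.185), Bcat_KO S3 (0.0551) or Bcat_KO S4 (0.107), and also with library-size scaling. Ctnnb1 was at 332 and 354 CPM in WT_Prmt1 and 378 and 384 in Prmt1_KO. Prmt1 (ENSMUSG00000109324, chromosome 7, 44975989 to 44986568, minus strand) went from 283 and 292 CPM in WT_Prmt1 to 118 and 112 in Prmt1_KO, where it fell by 1.33 ± 0.07 (1.001e-09). In the other experiment Prmt1 was at 322 and 334 CPM in WT, 272 in both Hoxa9_KO libraries, 310 and 301 in Bcat_KO, and 255 and 259 in dKO. It fell by 0.35 ± 0.07 in dKO (0.00206, but 0.0652 without WT S2). The value in Hoxa9_KO was -0.27 ± 0.07 (0.0290), a call lost without any 1 of the 4 libraries (0.130 without WT S1, 0.314 without WT S2, 0.149 without Hoxa9_KO S4, 0.114 without Hoxa9_KO S5). Counts cover the whole gene, and which exons the alleles delete is not given in the sources used here.

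**Figure D1:**
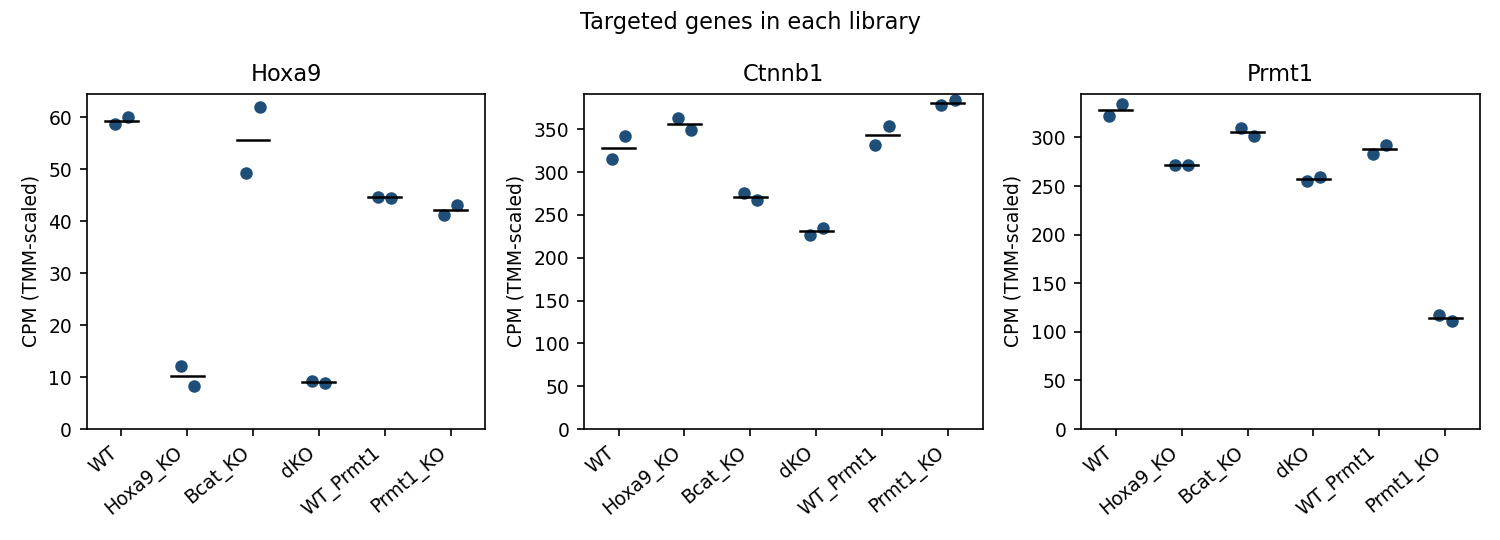
Hoxa9, Ctnnb1 and Prmt1 in each library (y axis, TMM-scaled CPM) by group, with a point per library and a bar at the group mean. Hoxa9 means were 10.3 in Hoxa9_KO and 9.07 in dKO against 59.3 in WT, Ctnnb1 means 271 in Bcat_KO and 231 in dKO against 328 in WT, and the Prmt1 mean 115 in Prmt1_KO against 288 in WT_Prmt1.

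The wild-type libraries differed from the knockouts in sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, was at 182 and 163 CPM in WT and 202 and 170 in WT_Prmt1, at 11.2 and 21.9 in Bcat_KO, and at 0.758 or lower in the other knockout libraries. Ddx3y, on the Y chromosome, was at 60.6 to 93.5 CPM in every knockout library and at 0.792 to 2.87 in the WT and WT_Prmt1 libraries. Each knockout-to-wild-type comparison below is therefore also one of male-typed with female-typed cells, whereas dKO against Hoxa9_KO and WT_Prmt1 against WT are not. Olfactory and vomeronasal receptor genes, which blood cells do not transcribe, gave 163 and 124 CPM in WT, 131 and 130.5 in WT_Prmt1, 80.4 and 56.2 in Hoxa9_KO, 79.9 and 78.9 in dKO, 73.4 and 66.7 in Prmt1_KO, and 15.1 and 11.6 in Bcat_KO.

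**Figure D2:**
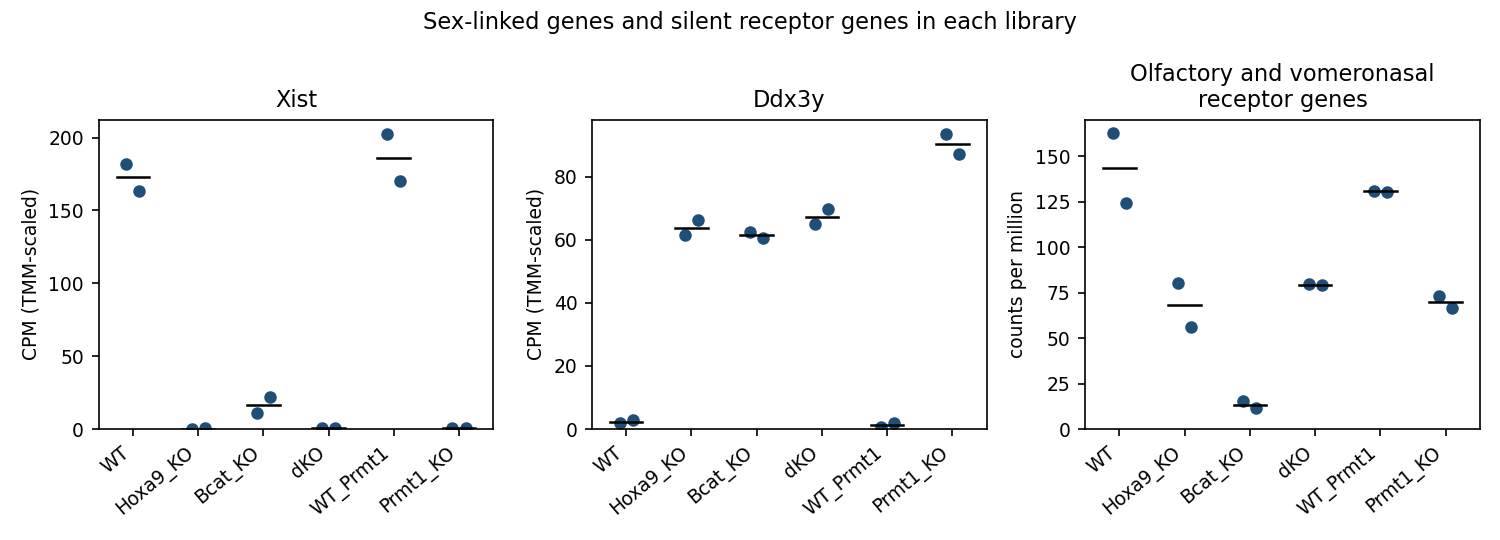
Xist and Ddx3y (y axis, TMM-scaled CPM) and the sum over olfactory and vomeronasal receptor genes (CPM) in each library by group, with a point per library and a bar at the group mean. Both wild-type groups had Xist at 163 or more and Ddx3y at 2.87 or less, and the Bcat_KO libraries had the lowest receptor signal, 15.1 and 11.6.

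In Hoxa9_KO LSK cells, genes of long-term stem cells and of the megakaryocyte lineage rose, and genes of multipotent and lymphoid-primed progenitors fell. Of 43 long-term HSC genes, 28 rose and 4 fell (29 and 6 adjusted over the list alone, median 0.80, camera adjusted p = 5.15e-19, and adjusted p = 0.189 with an estimated correlation). Tek, the angiopoietin receptor, rose from 12.8 to 52.7 CPM (2.03 ± 0.15, adjusted p = 1.88e-07). The adhesion molecule Esam rose by 1.51 ± 0.13 (1.91e-06). The 4 members that fell, named after their values were seen, were Cd34, Socs2, Gimap6 and Txnip (-0.95, -0.90, -0.56 and -0.46), and Cd34 is known to be low on adult mouse stem cells. Megakaryocyte and platelet markers rose in 10 of 20 cases and fell in none (12 and 1 adjusted over the list alone, median 1.37, 6.10e-15, and adjusted p = 0.0862 with an estimated correlation). They included the platelet integrin subunit Itgb3 (2.17 ± 0.13, 1.75e-08), P-selectin (Selp, 2.04 ± 0.14, 8.39e-07) and the granule-release factor Rab27b (1.86 ± 0.19, 8.97e-06).

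Progenitor genes moved the other way in Hoxa9_KO. Among 17 multipotent progenitor genes 6 fell and 1, Ccnd1, rose (8 and 1 adjusted over the list alone, median -0.66, 3.94e-07, and adjusted p = 0.326 with an estimated correlation). Cd27 fell from 138 to 65.3 CPM (-1.08 ± 0.08, 4.98e-07) and the myeloid transcription factor Cebpa from 71.7 to 23.9 (-1.58 ± 0.15, 4.63e-06). The value of Ccnd1 was 0.62, a call lost without WT S1, WT S2 or Hoxa9_KO S4 (up to 0.355, without Hoxa9_KO S4). Lymphoid-primed progenitor markers fell in 8 of 25 cases, with 1 rise (15 and 2 adjusted over the list alone, median -0.88, 2.54e-09, and adjusted p = 0.227 with an estimated correlation). They included the interleukin 7 receptor Il7r (-1.61 ± 0.27, 0.00151) and the kinase Lck (-0.88 ± 0.14, 0.000895). DNA replication genes fell in 6 of 60 cases and rose in none (10 and 0 adjusted over the list alone, median -0.21, 3.10e-07, and adjusted p = 0.424 with an estimated correlation), led by the sliding clamp Pcna (-0.53 ± 0.07, 0.000119). Of 40 mitosis genes 1 fell (0 adjusted over the list alone, median -0.30, 2.36e-06, and adjusted p = 0.588 with an estimated correlation). That gene was Cdk1 (-0.47 ± 0.13, 0.0327), whose call was lost without WT S1, WT S2 or Hoxa9_KO S4 (up to 0.302, without WT S2).

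Granulocyte, B cell, T and NK cell, erythroid and handling-response lists were called lower in Hoxa9_KO too, and each of these 5 calls was lost without at least 1 library. Of all 22 lists called in Hoxa9_KO, 12 kept their call in every fit without 1 library. Granulocyte markers fell in 2 of 25 cases and rose in none (3 and 0 adjusted over the list alone, median -0.71, 6.27e-05, and adjusted p = 0.574 with an estimated correlation). The call was lost without WT S1 (0.0748, median 0.023) or Hoxa9_KO S4 (0.733, median 0.11). B cell markers fell in 1 of 25 cases and rose in none (3 and 2 adjusted over the list alone, median -0.67, 0.00344, and adjusted p = 0.651 with an estimated correlation), lost without WT S2 (0.110) or Hoxa9_KO S4 (0.230). T cell, NK cell and innate lymphoid markers fell in 2 of 35 cases and rose in 1 (the same counts adjusted over the list alone, 0.0158, and adjusted p = 0.521 with an estimated correlation), lost without Hoxa9_KO S4 (0.1065). Erythroid markers fell in 1 of 28 cases and rose in 1 (4 and 3 adjusted over the list alone, median -1.02, 0.0324, and adjusted p = 0.535 with an estimated correlation), lost without WT S1 (0.390, median -0.28) or Hoxa9_KO S4 (0.348, median -0.68). In the list of immediate early and handling-response genes 6 of 27 fell and none rose (6 and 1 adjusted over the list alone, median -0.15, 0.00927, and adjusted p = 0.512 with an estimated correlation), lost without WT S1 (0.132, median -0.036). Hspa1b fell from 850 to 172 CPM (-2.31 ± 0.23, 0.00126).

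Single genes with large changes in Hoxa9_KO included another homeobox gene. Hoxb8 rose from 1.21 to 36.5 CPM (4.92 ± 0.54, 0.00120), and Hoxb6 from 1.05 to 9.37 (3.16 ± 0.48, 0.000501). Plscr2 (5.03 ± 0.69, 0.00294), Zg16 (4.60 ± 0.52, 2.78e-05) and the fibroblast activation protein Fap (4.50 ± 0.80, 0.00386) rose too, as did the Y-linked Ddx3y, Uty and Eif2s3y (4.74, 4.57 and 4.56). Matn4 rose from 0.583 to 40.9 CPM (0.0337), a call lost without any 1 of the 4 libraries (up to 0.225, without WT S2). Wfdc18 had 0 counts in Hoxa9_KO and 4.28 CPM in WT, 60.4-fold lower against a floor of 3 counts over the group. Here and for each fold given below as at least a value, that floor may be too low, since both mates appear to have been counted. Hnf4a, a transcription factor known from liver, fell from 22.8 to 0.947 CPM (-4.62 ± 0.37, 2.35e-06), the germ-cell helicase Ddx4 from 19.2 to 0.863 (-4.51 ± 0.42, 3.47e-06), Wfdc17 by 3.59 ± 0.29 (2.38e-06), Vldlr by 2.59 ± 0.36 (0.00175) and the endothelial sialomucin Emcn from 17.9 to 2.85 CPM (-2.65 ± 0.22, 7.76e-07). Postn (-3.59) kept its call except without Hoxa9_KO S5 (0.0549), and Emp1 (-2.56) lost it without any 1 library (up to 0.145, without Hoxa9_KO S4). In all, 757 genes rose and 392 fell of 17063 tested (DESeq2 called 1629). Without 1 library the total of 1149 became 521 (without WT S1), 624 (WT S2), 702 (Hoxa9_KO S4) or 948 (Hoxa9_KO S5).

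In Bcat_KO LSK cells, lymphoid, B cell and interferon-response genes fell and ribosome biogenesis and chromatin-regulator genes rose. Lymphoid-primed progenitor markers fell in 15 of 25 cases and rose in none (17 and 0 adjusted over the list alone, median -1.75, camera adjusted p = 1.12e-12, and adjusted p = 0.208 with an estimated correlation). They included the transcription factor Ets1 (-1.75 ± 0.15, 1.55e-06), Lck (-1.31 ± 0.14, 1.63e-05), Il7r (-2.54 ± 0.28, 2.83e-05) and Cnn3 (-1.75 ± 0.17, 2.84e-05). B cell markers fell in 16 of 25 cases and rose in none (18 and 0 adjusted over the list alone, median -1.70, 2.64e-09, and adjusted p = 0.376 with an estimated correlation). Spib, a transcription factor of B and plasmacytoid dendritic cells, fell from 14.7 to 0.458 CPM (-4.98 ± 0.37, 4.15e-06), and Cd79b by 1.58 ± 0.21 (0.000882). Type I interferon response genes fell in 18 of 44 cases and rose in none (24 and 0 adjusted over the list alone, 1.61e-08, and adjusted p = 0.0862 with an estimated correlation). Isg15 fell from 27.3 to 7.08 CPM (-1.95 ± 0.24, 7.51e-05). Interferon gamma and MHC class II genes fell in 11 of 29 cases and rose in none (18 and 0 adjusted over the list alone, median -0.55, 1.98e-06, and adjusted p = 0.424 with an estimated correlation). B2m fell by 0.81 ± 0.07 (1.81e-06). T cell, NK cell and innate lymphoid markers fell in 13 of 35 cases and rose in none (14 and 0 adjusted over the list alone, 2.67e-06, and adjusted p = 0.288 with an estimated correlation).

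Metabolic and chromatin groups also moved in Bcat_KO. Nuclear-encoded oxidative phosphorylation genes fell in 40 of 90 and rose in 1 (49 and 2 over the list alone, 1.10e-08, and 0.424 with an estimated correlation). They included Uqcrb (-0.86 ± 0.10, 1.75e-05) and Ndufb11 (-0.69 ± 0.09, 7.88e-05). Proteasome genes fell in 19 of 38 and rose in 1 (the same counts over the list alone, median -0.24, 0.000594, and 0.589 with an estimated correlation). Psma4 fell by 0.52 ± 0.08 (0.000402). Ribosome biogenesis genes rose in 14 of 39 and fell in none (15 and 0 over the list alone, median 0.24, 1.84e-05, and 0.353 with an estimated correlation). Nolc1 was at 0.52 ± 0.09 (0.00133) and the helicase Ddx21 at 0.48 ± 0.10 (0.00297). Ribosomal protein genes fell in 32 of 79 and rose in 2 (42 and 3 over the list alone, median -0.19, 0.00240, and 0.771 with an estimated correlation). Polycomb, trithorax and DNA methylation genes rose in 15 of 33 and fell in 2 (16 and 4 over the list alone, median 0.36, 9.70e-05, and 0.358 with an estimated correlation). Members were the maintenance methyltransferase Dnmt1 (0.76 ± 0.08, 7.44e-06), the histone methyltransferase Dot1l (1.16 ± 0.13, 1.47e-05) and Tet2 (2.48 ± 0.40, 0.00135). Known Wnt and β-catenin target genes gave no call as a list (3 of 24 higher, 6 lower, 7 lower adjusted over the list alone, camera adjusted p = 0.0999, and adjusted p = 0.410 with an estimated correlation). Lef1, one of them, went from 11.5 to 0.378 CPM (-4.87 ± 0.91, 0.00872), a call lost without WT S2, Bcat_KO S3 or Bcat_KO S4 (up to 0.0749, without Bcat_KO S3). Nkd2, a Wnt feedback inhibitor, had 0 counts in Bcat_KO and 2.24 CPM in WT, at least 55.2-fold lower.

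Erythroid and granulocyte lists were called lower in Bcat_KO, whose libraries also had the lowest receptor signal. Erythroid markers fell in 15 of 28 cases and rose in 1 (17 and 3 adjusted over the list alone, 6.32e-07, and adjusted p = 0.208 with an estimated correlation). Trim10 had 0 counts against 4.69 CPM in WT (at least 116-fold lower), Ermap fell by 3.44 ± 0.47 (0.000154), and carbonic anhydrase Car2 by 0.60 ± 0.07 (5.92e-05). Granulocyte markers fell in 8 of 25 cases and rose in 2 (14 and 4 adjusted over the list alone, 0.0132, and adjusted p = 0.747 with an estimated correlation), a call lost without Bcat_KO S3 (0.156). Endothelial and stromal markers fell in 5 of 24 cases and rose in 2 (8 and 3 adjusted over the list alone, 0.00267, and adjusted p = 0.217 with an estimated correlation). Markers of megakaryocytes and platelets rose in 4 of 20 cases and fell in none (the same counts adjusted over the list alone, median 0.18, 0.0227, and adjusted p = 0.424 with an estimated correlation), a call lost without WT S2 (0.0934, median 0.020), Bcat_KO S3 (0.200, median 0.083) or Bcat_KO S4 (0.0657, median 0.066). The neutrophil granule genes Ltf, Retnlg and Mmp9 (130 ± 111, 17.9 ± 15.3 and 15.4 ± 9.84 CPM, mean ± SD, in WT) had 0 counts in Bcat_KO and were at least 3214.5-fold, 442-fold and 379-fold lower, or 1284-fold, 174-fold and 207.5-fold without WT S1. Ngp, Chil3, Slc4a1 and Hba-a2 went from 287, 50.1, 34.9 and 75.4 CPM to 1.71, 0.126, 0.0635 and 0.552. The neutrophil genes, Slc4a1 and Hba-a2 all lost their calls when libraries were left out, with adjusted p up to 0.108 (Ltf), 0.131 (Retnlg), 0.106 (Mmp9), 0.117 (Chil3), 0.0940 (Slc4a1) and 0.105 (Hba-a2) without Bcat_KO S4, and 0.134 (Ngp) without Bcat_KO S3. Among the genes that rose were the mast cell protease Cma1 (0.0986 to 6.17 CPM, lost without WT S1 or WT S2, up to 0.122 without WT S2), Chac1 (3.93 ± 0.78, 0.00391), which degrades glutathione, and the Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y (4.68, 4.50, 4.40 and 3.96). The mitochondrial mt-Co2 and mt-Atp6 were called higher (5.89 and 4.45) but are uncertain, since they are known to have near-identical copies in the nuclear genome that can share their reads, which was not tested. mt-Co2 had 4 counts in each WT library and 475 and 379 in Bcat_KO, whereas mt-Co1 was at 10489 and 9380 CPM in WT and 9064 and 8890 in Bcat_KO. In all, 1277 genes rose and 1665 fell (DESeq2 called 3738). Higher calls were the majority with library-size scaling (1436 and 1377), at a mean of 5 CPM (1221 and 1096), with limma-voom (1414 and 1238) and with only the experiment fitted (1157 and 1064). The total of 2942 became 1333 without WT S1, 1312 without WT S2, 2115 without Bcat_KO S3 and 1651 without Bcat_KO S4.

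In dKO LSK cells, nearly the whole mitosis list and most DNA replication genes fell, while long-term stem cell and megakaryocyte genes rose. Of 40 mitosis and G2/M genes 36 fell and none rose (38 and 0 adjusted over the list alone, median -1.29, camera adjusted p = 7.74e-34, and adjusted p = 0.208 with an estimated correlation). The spindle kinesin Kif11 fell from 140 to 52.2 CPM (-1.43 ± 0.13, 2.11e-06), the kinase Cdk1 from 77.4 to 31.9 (-1.28 ± 0.13, 2.95e-06), Prc1 by 1.45 ± 0.15 (3.45e-06) and the kinetochore protein Cenpf from 40.9 to 12.98 CPM (-1.66 ± 0.18, 5.08e-06). DNA replication genes fell in 44 of 60 cases and rose in none (48 and 0 adjusted over the list alone, median -0.51, 2.94e-19, and adjusted p = 0.208 with an estimated correlation). They included Pcna (-0.89 ± 0.07, 1.62e-07), the polymerase δ catalytic subunit Pold1 (-0.65 ± 0.08, 1.81e-05), the ribonucleotide reductase subunit Rrm1 (-0.63 ± 0.08, 4.59e-05) and the helicase subunit Mcm4 (-0.56 ± 0.08, 7.77e-05). Genes of homologous recombination, the Fanconi pathway and fork protection fell in 18 of 49 cases and rose in none (18 and 1 adjusted over the list alone, median -0.33, 1.04e-06, and adjusted p = 0.167 with an estimated correlation). Uhrf1 fell by 1.28 ± 0.11 (1.21e-06) and the histone gene H2afx by 1.30 ± 0.14 (3.81e-05).

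Long-term HSC, megakaryocyte, multipotent and lymphoid-primed lists were called in dKO in the same directions as in Hoxa9_KO. Long-term HSC genes rose in 29 of 43 cases and fell in 4 (33 and 5 adjusted over the list alone, median 1.10, 5.15e-19, and adjusted p = 0.200 with an estimated correlation). They included Tek (2.40 ± 0.15, 1.36e-08), Pdzk1ip1 (1.67 ± 0.12, 1.04e-07), Esam (1.59 ± 0.13, 4.10e-07) and the receptor Neo1 (2.90 to 77.6 CPM, 4.75 ± 0.53, 0.000708). The 4 that fell were Cd34 (-1.71), Hlf (-0.55), Txnip (-0.49) and Gimap6 (-0.27). Hlf and Gimap6 lost their calls without WT S1, WT S2 or dKO S6 (up to 0.146 without WT S1 for Hlf and 0.374 without dKO S6 for Gimap6). Megakaryocyte and platelet markers rose in 14 of 20 cases and fell in none (16 and 0 adjusted over the list alone, median 1.95, 1.13e-15, and adjusted p = 0.0862 with an estimated correlation). Itgb3 rose by 2.32 ± 0.13 (4.04e-09), Selp by 2.33 ± 0.14 (1.07e-07) and the platelet glycoprotein Gp9 by 2.22 ± 0.18 (3.43e-07). Multipotent progenitor genes fell in 9 of 17 cases, and 1, Ccnd1, rose (the same counts adjusted over the list alone, median -0.77, 1.97e-10, and adjusted p = 0.217 with an estimated correlation). Cd34 fell from 740 to 226 CPM and Cd27 from 138 to 46.4 (-1.58 ± 0.09, 3.11e-09). Lymphoid-primed markers fell in 15 of 25 cases and rose in 3 (16 and 4 adjusted over the list alone, median -1.10, 7.93e-11, and adjusted p = 0.196 with an estimated correlation). Members were Cnn3 (-3.05 ± 0.19, 1.57e-07), the recombinases Rag1 (37.8 to 1.35 CPM, -4.81 ± 0.63, 0.00153) and Rag2 (-5.40 ± 0.90, 0.00127), and Lck (-1.45 ± 0.15, 2.76e-06).

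B cell genes split in dKO. Single genes that fell, named after their values were seen, were the transcription factor Pax5 (75.1 to 2.85 CPM, -4.72 ± 0.61, 0.00278), the surrogate light chain gene Vpreb3 (-4.63 ± 0.69, 0.00541) and Spib (-1.96 ± 0.31, 0.000707), with Vpreb1 (-4.75) called except without WT S2 (0.0591). In the B cell list 11 of 25 fell and 4 rose (12 and 4 adjusted over the list alone, median -0.91, 0.000675, and adjusted p = 0.603 with an estimated correlation). The 4 that rose, named after their values were seen, were Fcrla (1.93), Igkc (2.75), Jchain (2.29) and Ighm (2.12), and Jchain and the immunoglobulin genes are known to be abundant in plasma cells. Igkc lost its call without WT S1 (0.0974), Jchain without WT S1 or dKO S6 (up to 0.112, without WT S1), and Ighm without any 1 library (up to 0.193, without WT S1). Immunoglobulin segments took 8.34% of the counts in dKO S6 and 3.20% in dKO S7, against 0.645% and 1.35% in WT.

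RNA-processing genes fell in dKO as well. Of 47 genes for heterogeneous nuclear RNPs, SR proteins and Sm proteins, 26 fell and 2 rose (28 and 2 adjusted over the list alone, median -0.30, 2.85e-07, and adjusted p = 0.200 with an estimated correlation). The splicing factor Srsf7 fell by 0.95 ± 0.08 (8.17e-07) and Snrnp70 by 0.54 ± 0.07 (3.61e-05). Known Myc targets fell in 14 of 31 cases and rose in 1 (18 and 1 adjusted over the list alone, median -0.30, 2.31e-05, and adjusted p = 0.167 with an estimated correlation). They included Ran (-0.54 ± 0.07, 2.21e-05). In the list of immediate early and handling-response genes 9 of 27 fell and 4 rose (12 and 5 adjusted over the list alone, median -0.25, 0.00188, and adjusted p = 0.455 with an estimated correlation). Hspa1b, a member named after its values were seen, fell from 850 to 19.2 CPM (-5.47 ± 0.27, 1.25e-05), and so did Hspa1a from 317 to 9.29 (-5.09 ± 0.24, 2.91e-06), Hspa8 by 1.01 ± 0.06 (4.04e-09) and Hsp90aa1 by 0.92 ± 0.08 (4.07e-07). Hox genes and cofactors rose in 8 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone, 0.000123, and adjusted p = 0.295 with an estimated correlation). Hoxb8 rose from 1.21 to 41.0 CPM (5.09 ± 0.54, 0.000378) and Pbx3 up by 2.17 ± 0.21 (2.25e-06). The 1 that fell was Hoxa4 (-2.18), a call lost without any 1 library (up to 0.343, without WT S1). The Wnt target list gave no call in dKO against WT (2 of 24 higher, 5 lower, 6 lower adjusted over the list alone, camera adjusted p = 0.709, and adjusted p = 0.853 with an estimated correlation).

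Other large changes in dKO included Bcat1, a branched-chain amino acid transaminase whose symbol resembles the Bcat_KO label but which is a different gene from Ctnnb1. It fell from 16.7 to 0.270 CPM (-5.93 ± 0.48, 3.13e-07). Hnf4a (-5.29 ± 0.38, 4.08e-07) and the sodium channel subunit Scn4b (-5.84 ± 0.86, 0.00295) fell too, and Gfra2 went from 35.1 to 0.581 CPM (lost without WT S1 or WT S2, up to 0.0764 without WT S2). Plscr2 (5.36 ± 0.69, 0.000859), Slc13a2 (5.17 ± 1.09, 0.00364), Mab21l2 (5.05 ± 0.87, 0.000619) and Fap (4.72 ± 0.80, 0.00114) rose, as did Ddx3y and Eif2s3y (4.81 and 4.68). The mast cell genes Tpsb2 (0 counts in WT, at least 154-fold higher) and Cma1 (0.0986 to 8.79 CPM) and the genes Flrt1 (6.39) and Matn4 (5.52) were called with all 12 libraries fitted. Tpsb2 lost its call without any 1 library (up to 0.187, without WT S2), Cma1 and Flrt1 without WT S1 or WT S2 (up to 0.0959 without WT S2 and 0.113 without WT S1), and Matn4 without WT S1, WT S2 or dKO S7 (up to 0.161, without WT S2). Basophil, mast cell and eosinophil markers rose in 4 of 17 cases and fell in none (the same counts adjusted over the list alone, 0.0352, and adjusted p = 0.603 with an estimated correlation), a call lost without WT S2 (0.166) or dKO S6 (0.413). In all, 1562 genes rose and 1454 fell (DESeq2 called 3499). Lower calls were the majority with library-size scaling (1359 higher and 1597 lower), scaling without mitochondrial and haemoglobin genes (1499 and 1520), without dKO S6 (1451 and 1488) and without X and Y genes (1451 and 1470). The total of 3016 became 1918 without WT S1, 1698 without WT S2, 2939 without dKO S6 and 1776 without dKO S7.

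dKO cells had lower cell cycle genes than Hoxa9_KO cells, in libraries that were all male-typed. Mitosis genes fell in 22 of 40 cases and rose in none (37 and 0 adjusted over the list alone, median -0.99, camera adjusted p = 1.86e-53, and adjusted p = 0.167 with an estimated correlation). They included Cenpf (37.4 to 12.98 CPM, -1.53 ± 0.18, 0.000379), Kif11 (109 to 52.2, -1.06 ± 0.13, 0.000723), the checkpoint kinase Bub1b (118 to 55.0, -1.10 ± 0.13, 0.00132) and Hmmr (-1.08 ± 0.15, 0.00132). DNA replication genes fell in 8 of 60 cases and rose in none (28 and 0 adjusted over the list alone, median -0.29, 9.12e-18, and adjusted p = 0.217 with an estimated correlation). Recombination and Fanconi genes fell in 3 of 49 cases (9 adjusted over the list alone, median -0.35, 4.93e-11, and adjusted p = 0.102 with an estimated correlation). H2afx fell by 0.89 ± 0.14 (0.00670), and Uhrf1 by 0.62, a call lost without Hoxa9_KO S5 or dKO S7 (up to 0.0745, without Hoxa9_KO S5). Multipotent progenitor genes fell in 2 of 17 cases (6 adjusted over the list alone, median -0.49, 6.43e-07, and adjusted p = 0.333 with an estimated correlation), and megakaryocyte markers rose in 1 of 20 (3 adjusted over the list alone, median 0.42, 1.58e-06, and adjusted p = 0.180 with an estimated correlation). The granulocyte list was called higher with no single member called of 25 (median 1.59, 2.92e-08, and adjusted p = 0.424 with an estimated correlation).

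Other lists of cell types were also called between dKO and Hoxa9_KO, with few or no single members called. Lymphoid-primed progenitor markers fell in 2 of 25 cases and rose in none (10 and 1 adjusted over the list alone, median -0.23, 2.45e-07, and adjusted p = 0.276 with an estimated correlation). B cell markers fell in 1 of 25 cases and rose in none (6 and 0 adjusted over the list alone, median -0.36, 0.00804, and adjusted p = 0.678 with an estimated correlation), a call lost without Hoxa9_KO S5 (0.167, median 0.012) or dKO S7 (0.836, median near 0). Long-term HSC genes rose in 3 of 43 cases and fell in 1 (9 and 1 adjusted over the list alone, median 0.30, 2.23e-06, and adjusted p = 0.404 with an estimated correlation), a call lost without dKO S7 (0.344, median 0.029). Erythroid markers were called higher with no single member called of 28 (the same counts adjusted over the list alone, median 0.53, 6.57e-05, and adjusted p = 0.264 with an estimated correlation). Basophil, mast cell and eosinophil markers rose in 1 of 17 cases and fell in none (2 and 0 adjusted over the list alone, 2.65e-06, and adjusted p = 0.308 with an estimated correlation), a call lost without dKO S6 (0.137). T cell, NK cell and innate lymphoid markers rose in 2 of 35 cases and fell in none (3 and 1 adjusted over the list alone, 0.00461, and adjusted p = 0.458 with an estimated correlation), a call lost without Hoxa9_KO S4 (0.0682) or dKO S6 (0.965). Endothelial and stromal markers were called higher with 0 of 24 higher and 1 lower (1 and 1 adjusted over the list alone, 0.0236, and adjusted p = 0.344 with an estimated correlation), a call lost without Hoxa9_KO S4 (0.391) or dKO S6 (0.444).

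Ctnnb1 itself was lower in dKO than in Hoxa9_KO (-0.63 ± 0.07, adjusted p = 0.000379), and Hoxa9 was at -0.17 ± 0.16 (0.769). Bcat1 fell from 5.89 to 0.270 CPM (-4.43 ± 0.47, 0.000220), the scaffold protein Akap12 from 10.8 to 1.54 (-2.81 ± 0.31, 0.000379), Cnn3 by 1.32 ± 0.18 (0.00230), the pericyte receptor gene Pdgfrb by 1.47 ± 0.17 (0.000379), Hspa1b by 3.16 ± 0.24 (0.00186) and Hspa1a by 2.77 ± 0.22 (0.00132). Bace2 rose from 0.398 to 7.74 CPM (4.29 ± 0.69, 0.00323). Some calls were lost without 1 library while the value kept its sign: Krt83 (4.07, and 3.34 without Hoxa9_KO S4 and 3.47 without dKO S6, up to 0.0997 without dKO S6), Rgs7bp (3.19, and 3.17 without Hoxa9_KO S5, 0.0606) and Sh3gl3 (2.95, and 2.59 without Hoxa9_KO S5 and 2.41 without dKO S7, up to 0.0700 without Hoxa9_KO S5). Cma1 (4.37, and 4.14 to 4.74 without 1 library) and Rag1 (-3.43, and -4.11 to -2.96) were lost without any 1 library (up to 0.393 without Hoxa9_KO S4 and 0.228 without dKO S7). In all, 71 genes rose and 227 fell (DESeq2 called 621, and 2120 genes had an unadjusted p under 0.05). The total of 298 became 168 without Hoxa9_KO S5, 189 without dKO S7 and 607 without dKO S6, and was 3 when only these 4 libraries were fitted.

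dKO cells had lower cell cycle genes than Bcat_KO cells too, and higher stem cell, megakaryocyte and interferon genes. A technical offset of the Bcat_KO libraries would enter these values. Mitosis genes fell in 37 of 40 cases and rose in 1 (38 and 1 adjusted over the list alone, median -1.21, camera adjusted p = 2.33e-26, and adjusted p = 0.235 with an estimated correlation). Cenpf fell from 59.1 to 12.98 CPM (-2.19 ± 0.18, 3.83e-07). Replication genes fell in 40 of 60 cases and rose in 1 (44 and 1 adjusted over the list alone, median -0.45, 1.40e-12, and adjusted p = 0.301 with an estimated correlation). The helicase subunit Mcm5 fell by 0.67 ± 0.08 (2.37e-05). Ribosome biogenesis genes fell in 28 of 39 cases (32 lower and 1 higher adjusted over the list alone, median -0.42, 2.53e-11, and adjusted p = 0.200 with an estimated correlation). Nop56 fell by 0.78 ± 0.08 (3.51e-06). Long-term HSC genes rose in 31 of 43 cases and fell in 4 (34 and 4 adjusted over the list alone, median 1.01, 6.24e-13, and adjusted p = 0.256 with an estimated correlation). Pdzk1ip1 rose by 1.89 ± 0.12 (4.10e-08). Megakaryocyte and platelet markers rose in 15 of 20 cases and fell in none (16 and 0 adjusted over the list alone, median 1.54, 5.86e-09, and adjusted p = 0.148 with an estimated correlation). Type I interferon response genes rose in 23 of 44 cases and fell in 1 (26 and 1 adjusted over the list alone, 4.22e-07, and adjusted p = 0.0905 with an estimated correlation). They included Ly6a, which encodes Sca1 (74.0 to 177 CPM, 1.26 ± 0.11, 1.41e-06). Hoxb8 (41.0 CPM in dKO) and Krt83 (7.54 CPM) had 0 counts in Bcat_KO and were at least 1010.2-fold and 186-fold higher in dKO (122-fold for Krt83 without dKO S6). Ltf, Retnlg and Mmp9 also had 0 counts in Bcat_KO and were at least 5626-fold, 469.7-fold and 420.2-fold higher, with calls lost without Bcat_KO S3 or S4 and, for Retnlg and Mmp9, dKO S7 as well (up to 0.0623, 0.0909 and 0.0699, each without Bcat_KO S4). Retnlg was also lost without dKO S6. Hnf4a fell by 5.53 ± 0.38 (3.83e-07). mt-Co2, mt-Atp6 and mt-Co3 were called lower (-6.65, -5.05 and -4.61) with the same untested possibility of shared reads, and mt-Co1 was at 7751 and 6586 CPM in dKO. Rpl39l (-4.25) lost its call without any 1 library (up to 0.208, without dKO S7). In all, 2760 genes rose and 2042 fell (DESeq2 called 5494), and with library-size scaling 2279 rose and 2463 fell.

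Marker lists of other cell types were called higher in dKO than in Bcat_KO. A group had 3 counts or fewer for 8 of 24 endothelial, 5 of 35 T and NK cell and 4 of 25 granulocyte members. The other lists had 1 such member at most. Erythroid markers rose in 17 of 28 and fell in 1 (19 and 1 over the list alone, 1.62e-07, and 0.176 with an estimated correlation). T cell, NK cell and innate lymphoid markers rose in 14 of 35 and fell in 1 (15 and 2 over the list alone, 0.000224, and 0.383 with an estimated correlation). Granulocyte markers rose in 13 of 25 cases and fell in 4 (13 and 5 adjusted over the list alone, 0.0272, and adjusted p = 0.770 with an estimated correlation), a call lost without Bcat_KO S3 (0.187), Bcat_KO S4 (0.0533) or dKO S6 (0.141). Monocyte, macrophage and dendritic cell markers rose in 8 of 26 cases and fell in 1 (9 and 1 adjusted over the list alone, 0.0424, and adjusted p = 0.709 with an estimated correlation), a call lost without Bcat_KO S3 (0.114), Bcat_KO S4 (0.0610) or dKO S6 (0.565). B cell markers rose in 9 of 25 cases and fell in none (the same counts adjusted over the list alone, median 1.13, 0.0318, and adjusted p = 0.747 with an estimated correlation), a call lost without Bcat_KO S3 (0.355, median 0.72) or dKO S6 (0.8998, median 0.30). Endothelial and stromal markers rose in 8 of 24 cases and fell in 2 (9 and 2 adjusted over the list alone, 0.00737, and adjusted p = 0.276 with an estimated correlation), a call lost without Bcat_KO S3 (0.113) or dKO S6 (0.0504).

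**Figure D3:**
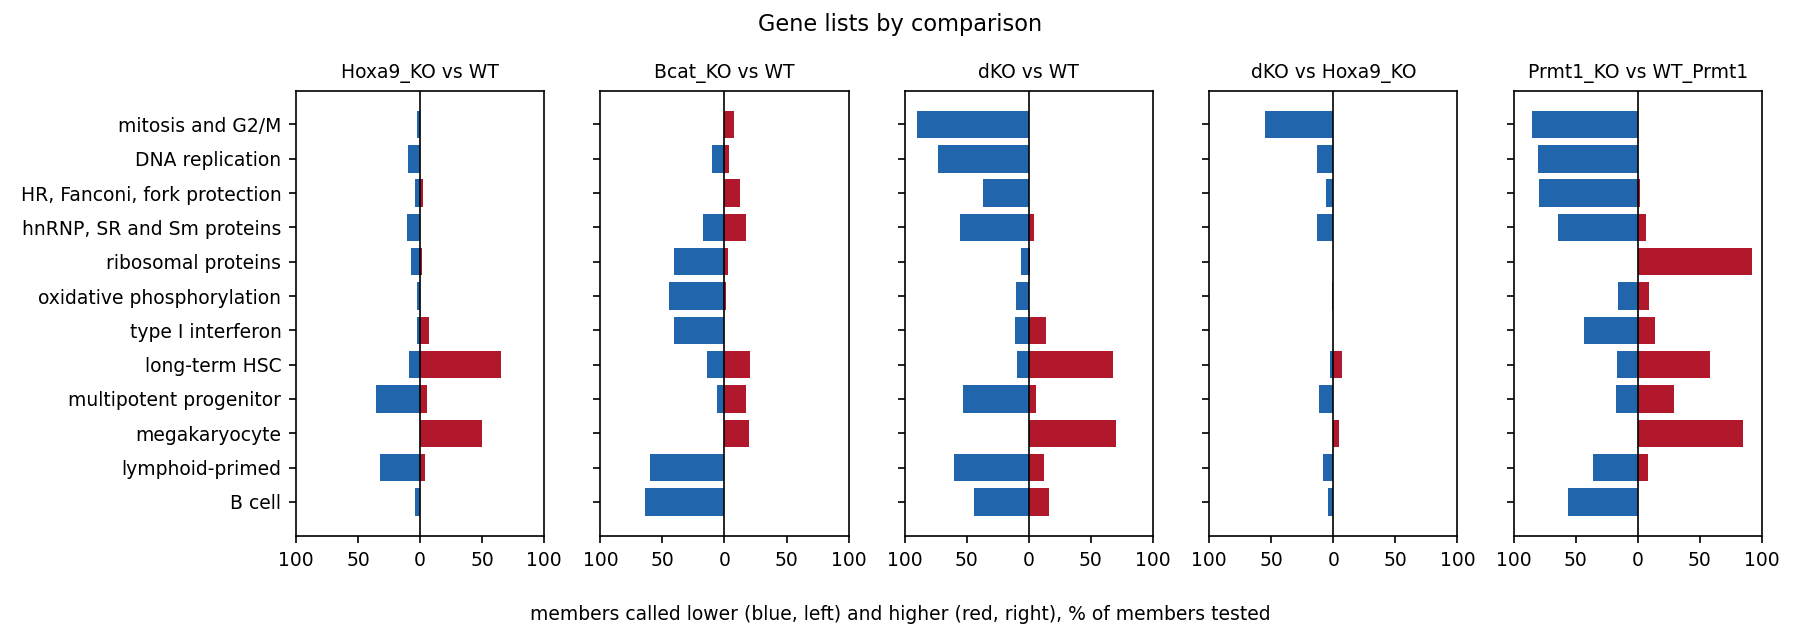
Share of tested members called lower (blue bars, left) and higher (red bars, right), in percent (x axis), for 12 gene lists (y axis) in 5 comparisons. In dKO against WT 36 of 40 mitosis genes were lower and 29 of 43 long-term HSC genes higher, and in Prmt1_KO against WT_Prmt1 34 of 40 mitosis genes were lower and 73 of 79 ribosomal protein genes higher.

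The dKO was compared with the sum of the changes in the single knockouts. Mitosis genes were below the sum in 17 of 40 cases and above it in none (24 and 0 adjusted over the list alone, median -0.86, camera adjusted p = 9.12e-18, and adjusted p = 0.344 with an estimated correlation). They included Cenpf (-2.06 ± 0.24, 9.21e-05), Kif11 (-1.05 ± 0.18, 0.00270) and Prc1 (-1.11 ± 0.21, 0.00365). Recombination and Fanconi genes were below it in 8 of 49 (10 over the list alone, median -0.48, 4.13e-07, and 0.167 with an estimated correlation). Brca2 was at -1.01 ± 0.17 (0.00189). Interferon gamma and MHC class II genes were above it in 7 of 29 (21 over the list alone, median 0.90, 2.03e-09, and 0.353 with an estimated correlation). B2m was at 0.95 ± 0.10 (3.30e-05). Ribosomal protein genes, which fell in Bcat_KO, were above it in 32 of 79 and below it in 1 (48 and 1 over the list alone, 1.37e-06, and 0.642 with an estimated correlation). Rpl30 was at 0.71 ± 0.10 (0.000357). Oxidative phosphorylation genes were above it in 22 of 90 cases (34 above and 1 below adjusted over the list alone, 1.21e-06, and adjusted p = 0.512 with an estimated correlation), and erythroid markers in 14 of 28 (17 and 1 adjusted over the list alone, 4.36e-11, and adjusted p = 0.151 with an estimated correlation). Car2 was at 0.77 ± 0.11 (0.000353). Known Wnt and β-catenin target genes were above the sum in 2 of 24 cases and below it in 1 (the same counts adjusted over the list alone, 0.0317, and adjusted p = 0.309 with an estimated correlation), a call lost without WT S2 (0.110), Hoxa9_KO S4 (0.0971), Bcat_KO S4 (0.133) or dKO S6 (0.0507). Ctnnb1 was at -0.35 ± 0.10 (0.0462), a call lost without any 1 of the 8 libraries (up to 0.292, without WT S1). In all, 774 genes were above and 665 below the sum (625 and 878 with library-size scaling, where the median of all genes was -0.04). More genes were below the sum also at a mean of 5 CPM (592 and 641), with limma-voom (484 and 568), with only the groups compared (413 and 542) and without dKO S6 (583 and 626). The total of 1439 became 670 without WT S1, 826 without WT S2 and 910 without Hoxa9_KO S4. Every single knockout carried the Y-linked transcripts, so their sum counts that difference from WT 2 times, and Ddx3y departed by -4.60 ± 0.31 (6.70e-06).

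Marker lists of other cell types lay above the sum as well. Granulocyte markers were above the sum in 5 of 25 cases and below it in 1 (13 and 1 adjusted over the list alone, 2.55e-07, and adjusted p = 0.458 with an estimated correlation). Lymphoid-primed progenitor markers were above the sum in 5 of 25 cases and below it in none (8 and 0 adjusted over the list alone, median 0.73, 0.000117, and adjusted p = 0.422 with an estimated correlation). B cell markers were above the sum in 5 of 25 cases and below it in none (7 and 0 adjusted over the list alone, median 1.35, 1.08e-05, and adjusted p = 0.512 with an estimated correlation). T cell, NK cell and innate lymphoid markers were above the sum in 13 of 35 cases and below it in none (16 and 0 adjusted over the list alone, 3.23e-08, and adjusted p = 0.217 with an estimated correlation). Endothelial and stromal markers were above the sum in 4 of 24 cases and below it in 1 (5 and 2 adjusted over the list alone, 5.90e-05, and adjusted p = 0.167 with an estimated correlation).

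Most calls in Hoxa9_KO were shared with dKO. The 2 comparisons had 1036 genes called in the same direction (701 higher, 335 lower) and 1 in opposite directions, where independent calls would give 69.3 higher and 33.4 lower. Hoxa9_KO and Bcat_KO shared 409 (237 and 172) with 35 opposite, and Bcat_KO and dKO shared 747 (380 and 367) with 161 opposite. The 3 comparisons use the same 2 WT libraries, and each sets male-typed against female-typed cells, so part of the overlap may come from both. In 20 simulations of unchanged groups against those libraries the shared count was 2 at most, and the covariance of the log2 changes across genes was 0.269 for Hoxa9_KO and dKO against 1.12 measured, 0.267 for Hoxa9_KO and Bcat_KO against 0.848, and 0.271 for Bcat_KO and dKO against 0.742. Pearson's r of the same pairs was 0.517 simulated and 0.684 measured, 0.521 and 0.361, and 0.533 and 0.300, so it was below the simulated value for both pairs with Bcat_KO. Genes are not independent replicates, and the WT libraries were not split, since each part would hold 1 library.

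In Prmt1_KO LSK cells, DNA replication, mitosis and DNA repair genes fell and ribosomal protein, megakaryocyte and glycolysis genes rose. DNA replication genes fell in 48 of 60 cases and rose in none (50 and 0 adjusted over the list alone, median -0.71, camera adjusted p = 9.26e-19, and adjusted p = 0.217 with an estimated correlation). Thymidylate synthase Tyms fell from 136 to 26.6 CPM (-2.35 ± 0.12, 3.66e-10), Pcna from 647 to 314 (-1.04 ± 0.07, 8.50e-09), Pola1 by 1.36 ± 0.09 (9.42e-09) and the ligase Lig1 by 1.23 ± 0.08 (1.13e-08). Recombination and Fanconi genes fell in 39 of 49 cases and rose in 1 (40 and 1 adjusted over the list alone, median -0.86, 1.38e-11, and adjusted p = 0.101 with an estimated correlation). Brca2 fell by 1.97 ± 0.13 (6.25e-09). Mitosis genes fell in 34 of 40 cases and rose in none (35 and 0 adjusted over the list alone, median -0.98, 2.00e-15, and adjusted p = 0.364 with an estimated correlation). Kif11 fell from 171 to 58.6 CPM (-1.55 ± 0.13, 2.58e-07) and Bub1 by 1.48 ± 0.15 (2.45e-06). Ribosomal protein genes rose in 73 of 79 cases and fell in none (74 and 0 adjusted over the list alone, median 0.46, 8.99e-17, and adjusted p = 0.411 with an estimated correlation). They included Rpl3 (0.91 ± 0.06, 1.15e-08) and Rpl13a (1.54 ± 0.10, 7.06e-09). Glycolysis genes rose in 16 of 26 cases and fell in 2 (18 and 2 adjusted over the list alone, median 0.40, 5.11e-05, and adjusted p = 0.208 with an estimated correlation). Hexokinase Hk1 rose by 1.14 ± 0.07 (6.25e-09) and Pfkfb3 by 1.40 ± 0.12 (1.68e-07).

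Genes of several blood lineages changed in Prmt1_KO. Megakaryocyte and platelet markers rose in 17 of 20 cases and fell in none (the same counts adjusted over the list alone, median 2.38, 1.20e-14, and adjusted p = 0.0862 with an estimated correlation). Itgb3 rose from 31.6 to 303 CPM (3.26 ± 0.13, 3.64e-11), Selp from 5.80 to 139 (4.59 ± 0.16, 1.66e-10) and Gp9 by 2.80 ± 0.19 (1.28e-08). Basophil, mast cell and eosinophil markers rose in 10 of 17 cases and fell in none (the same counts adjusted over the list alone, 1.25e-05, and adjusted p = 0.326 with an estimated correlation): the IgE receptor gene Fcer1a stood at 0.0566 CPM (2 counts in WT_Prmt1) and 12.4 CPM in Prmt1_KO, granzyme Gzmb rose by 6.65 ± 0.90 (0.000366), and Cma1 (0 counts in WT_Prmt1, 9.68 CPM in Prmt1_KO) was at least 129-fold higher. Granulocyte markers rose in 9 of 25 cases and fell in none (10 and 0 adjusted over the list alone, median 1.57, 0.000284, and adjusted p = 0.618 with an estimated correlation). Proteinase 3 (Prtn3) rose by 2.81 ± 0.23 (7.24e-05). B cell markers fell in 14 of 25 cases and rose in none (the same counts adjusted over the list alone, median -1.68, 1.39e-06, and adjusted p = 0.458 with an estimated correlation). Spib fell from 77.7 to 9.31 CPM (-3.06 ± 0.31, 7.51e-06). Lymphoid-primed progenitor markers fell in 9 of 25 cases and rose in 2 (11 and 2 adjusted over the list alone, median -0.44, 0.0383, and adjusted p = 0.644 with an estimated correlation), a call lost without WT_Prmt1 S11 (0.0569), Prmt1_KO S8 (0.0715) or Prmt1_KO S9 (0.0538). Rag1, the lymphoid recombinase, fell by 5.17 ± 0.66 (0.000620). Long-term HSC genes rose in 25 of 43 cases and fell in 7 (28 and 10 adjusted over the list alone, median 0.70, 6.69e-06, and adjusted p = 0.422 with an estimated correlation). Esam rose by 1.88 ± 0.14 (2.38e-08), while the cytokine-signalling inhibitor Socs2 fell from 253 to 11.4 CPM (-4.48 ± 0.18, 2.53e-10).

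RNA-binding protein, interferon and NF-kB genes changed in Prmt1_KO too. Genes for heterogeneous nuclear RNPs, SR and Sm proteins, among which arginine methylation targets are known, fell in 30 of 47 cases and rose in 3 (the same counts adjusted over the list alone, median -0.37, 8.00e-06, and adjusted p = 0.217 with an estimated correlation). Hnrnpa2b1 fell from 1857 to 1058 CPM (-0.81 ± 0.06, 2.32e-08) and Taf15 by 1.45 ± 0.11 (9.70e-08), while Hnrnpdl rose by 1.19 ± 0.10 (1.87e-07). Type I interferon response genes fell in 19 of 44 cases and rose in 6 (21 and 6 adjusted over the list alone, median -0.42, 0.00280, and adjusted p = 0.200 with an estimated correlation). Oas1a fell by 1.07 ± 0.13 (8.59e-06), whereas Ly6a (Sca1) rose by 1.61 ± 0.12 (2.59e-08). NF-kB and inflammatory genes rose in 11 of 26 cases and fell in none (12 and 1 adjusted over the list alone, median 0.66, 0.000404, and adjusted p = 0.424 with an estimated correlation). Bcl3 rose from 7.82 to 45.4 CPM (2.54 ± 0.26, 2.12e-06) and Tnf by 1.30 ± 0.17 (4.71e-05). Other arginine methyltransferase genes gave no call as a list (1 of 10 higher and 3 lower, the same counts adjusted over the list alone, camera adjusted p = 0.353, and adjusted p = 0.618 with an estimated correlation). Prmt7 fell from 59.2 to 29.7 CPM (1.83e-06) and Prmt3 from 78.2 to 39.1 (1.06e-05).

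Among the genes with the largest changes in Prmt1_KO, Trnp1 rose from 0.191 to 29.6 CPM (7.19 ± 0.49, 8.10e-08) and Clca3a1 from 1.44 to 91.2 (5.97 ± 0.21, 8.79e-12). Smoc2 and the metallothionein Mt2 stood at 0.0566 and 0.0674 CPM (2 and 3 counts) in WT_Prmt1 and at 16.2 and 6.06 CPM in Prmt1_KO. The Y-linked Uty, Ddx3y, Kdm5d and Eif2s3y were at 7.11, 6.08, 5.77 and 5.70, and Tpsb2 (6.30) lost its call without any 1 library (up to 0.186, without WT_Prmt1 S10). The collagen gene Col1a1 fell from 229 to 1.52 CPM (-7.23 ± 0.67, 0.000249), Hspa1b from 603 to 3.59 (-7.39 ± 0.30, 1.43e-06), and Xcr1, a chemokine receptor of cross-presenting dendritic cells, fell too (-6.09 ± 0.70, 1.84e-05), with Tlr11 (-6.40 ± 1.30, 0.00369), the nuclease gene Dnase1l3 (-6.36 ± 0.99, 0.00161) and Ccn3 (-6.20 ± 1.09, 0.00223). Tnfrsf19 went from 11.9 to 0.0613 CPM (2 counts). Col1a1, Xcr1, Dnase1l3 and Ccn3 were at 229, 17.95, 22.0 and 18.4 CPM in WT_Prmt1 but at 2.48, 2.87, 3.22 and 0.829 in the WT of the other experiment, where Ccl22 was at 0.453. The chemokine gene Ccl22 (12.03 CPM in WT_Prmt1) had 0 counts in Prmt1_KO, at least 155-fold lower, and lost its call without any 1 library (up to 0.176, without Prmt1_KO S9), as did Bcl2a1d (5.47 to 0.0446 CPM, up to 0.188 without Prmt1_KO S8). Fxyd6 (-6.67) lost it without Prmt1_KO S9 (0.0867), and Gfra2 (-6.07) without Prmt1_KO S8 or S9 (up to 0.0843, without S8). In all, 2826 genes rose and 2728 fell (DESeq2 called 5900). With only the groups compared the split was 3378 and 3462, and with library-size scaling it was 2052 and 3592, and the median of all genes moved to -0.17, which the changes above are to be read against.

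Genes that moved in dKO tended to move the same way in Prmt1_KO, a comparison that bears on the link to Prmt1 named in the title. Each experiment was fitted on its own for it, over 14046 genes. The 1297 genes higher in dKO had a median of 0.53 in Prmt1_KO (camera p = 3.84e-19, and p = 0.00377 with an estimated correlation), and 78.0% had the same sign. Of them 751 were also called higher in Prmt1_KO and 108 lower, where independence would give 307.9 called higher. The 1268 genes lower in dKO had a median of -0.50 (3.84e-21, and p = 0.0196 with an estimated correlation), 80.5% with the same sign, 826 called lower and 125 higher, where independence would give 306.8. Without WT S1, WT S2 or dKO S7 the higher set held 710, 657 or 790 genes, of which 448, 408 or 502 were called higher in Prmt1_KO and 47, 42 or 57 lower (168, 155 or 187 higher under independence). The lower set then held 650, 549 or 672 genes, of which 475, 379 or 483 were called lower and 62, 75 or 75 higher (157, 133 or 162 lower under independence). With the 100 smallest p per direction the medians were 1.24 and -0.96, and without X and Y genes 0.52 and -0.51. Across genes, which are not independent replicates, Pearson's r was 0.229 (0.133 without WT S2, and 0.0747 with no filter on low counts) and Spearman's rho 0.338 (0.130 with no filter). Both contrasts set male-typed against female-typed cells.

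**Figure D4:**
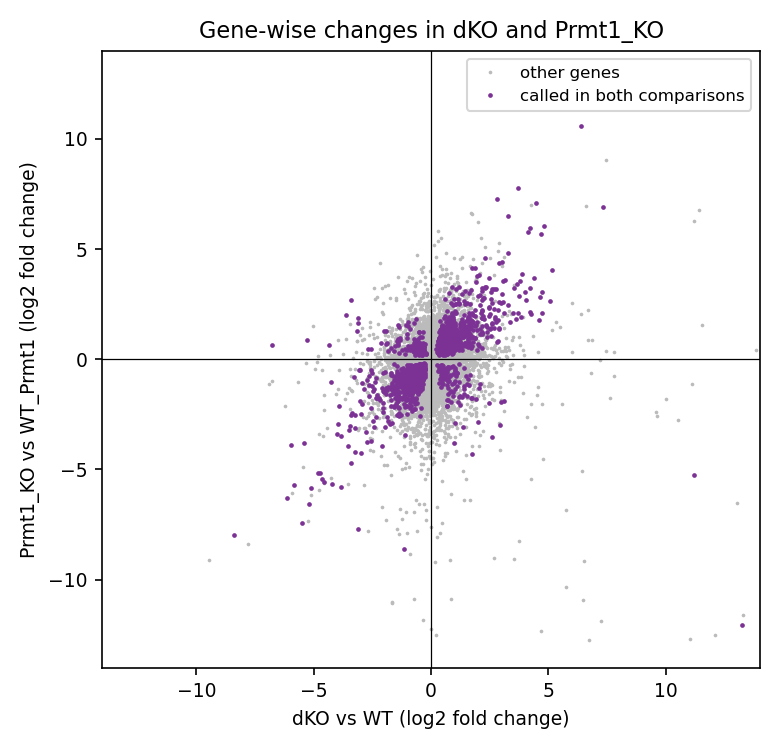
Each gene's log2 fold change in dKO against WT (x axis) and in Prmt1_KO against WT_Prmt1 (y axis), with a point per gene. Points are purple for genes called in both and grey for all other genes. Of the genes called higher in dKO 751 were called higher in Prmt1_KO, and of those called lower 826 were called lower.

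The change in dKO also differed from that in Prmt1_KO, in ribosomal, progenitor and inflammatory genes. Ribosomal protein genes had a lower change in dKO in 71 of 79 cases and a higher one in none (74 and 0 adjusted over the list alone, median difference -0.52, camera adjusted p = 9.62e-21, and adjusted p = 0.364 with an estimated correlation). Rpl13a was at -1.78 ± 0.14 (3.57e-07). Multipotent progenitor genes had a lower one in 9 of 17 and a higher one in 1 (12 and 1 over the list alone, median -1.45, 3.34e-09, and 0.256 with an estimated correlation). Cd27 was at -1.95 ± 0.12 (1.96e-08) and Ccnd1 at 1.71 ± 0.23 (7.75e-05). NF-kB and inflammatory genes had a lower one in 9 of 26 and a higher one in 2 (10 and 3 over the list alone, 8.74e-05, and 0.383 with an estimated correlation). Tnf was at -3.31 ± 0.24 (1.87e-06). Recombination and Fanconi genes fell less in dKO, with a higher change in 10 of 49 and a lower one in none (the same counts over the list alone, median 0.34, 0.000953, and 0.288 with an estimated correlation). Brca2 was at 1.92 ± 0.18 (1.76e-06). Type I interferon genes had a higher change in dKO in 17 of 44 and a lower one in 6 (19 and 6 over the list alone, median 0.60, 0.00200, and 0.196 with an estimated correlation). Oas3 was at 1.84 ± 0.22 (2.37e-05). Socs2 differed by 4.45 ± 0.23 (1.96e-08) and Prmt1 by 0.98 ± 0.10 (5.55e-06). The WT groups differed in 1294 genes, Socs2 among them (below), and that baseline enters this contrast. In all, 1353 genes had a higher and 1323 a lower change in dKO, a near-equal split that turned in other settings, as with RLE size factors (1318 and 1367). With library-size scaling the split was 1720 and 984, and the median of all genes was 0.14.

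Marker lists of cell types differed too. Granulocyte markers had a lower change in dKO in 4 of 25 and a higher one in none (5 and 0 over the list alone, median -1.09, 0.000886, and 0.646 with an estimated correlation). Megakaryocyte and platelet markers had a lower change in dKO in 6 of 20 and a higher one in 1 (7 and 1 over the list alone, median -0.90, 0.00168, and 0.326 with an estimated correlation). Basophil, mast cell and eosinophil markers had a lower change in dKO in 4 of 17 and a higher one in none (7 and 0 over the list alone, 0.00138, and 0.410 with an estimated correlation). Lymphoid-primed progenitor markers had a lower change in dKO in 6 of 25 and a higher one in none (7 and 1 over the list alone, median -0.51, 0.000600, and 0.431 with an estimated correlation). B cell markers had a higher change in dKO in 3 of 25 cases and a lower one in none (4 and 1 adjusted over the list alone, median 1.10, 0.0153, and adjusted p = 0.718 with an estimated correlation), a call lost without dKO S6 (0.745, median 0.16).

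The WT libraries of the 2 experiments, both female-typed, differed in stem cell, megakaryocyte and dendritic cell genes. Long-term HSC genes were lower in WT_Prmt1 in 20 of 43 cases and higher in 5 (23 and 6 adjusted over the list alone, median -0.56, camera adjusted p = 5.83e-08, and adjusted p = 0.350 with an estimated correlation), with the transcription factor Gata2 at 230 CPM in WT and 91.0 in WT_Prmt1 (-1.34 ± 0.10, 2.57e-07), while Socs2 was higher (26.4 and 253 CPM, 3.26 ± 0.17, 1.89e-08). Megakaryocyte and platelet markers were lower in 8 of 20 cases and higher in 1 (11 and 1 adjusted over the list alone, median -1.12, 1.44e-09, and adjusted p = 0.148 with an estimated correlation). Selp was at -2.45 ± 0.16 (2.94e-07). Monocyte, macrophage and dendritic cell markers were higher in 6 of 26 cases and lower in none (16 and 0 adjusted over the list alone, 7.42e-14, and adjusted p = 0.217 with an estimated correlation). Bst2 was at 1.39 ± 0.12 (2.67e-06) and the dendritic cell receptor Clec9a at 2.49 ± 0.34 (0.000173). Erythroid markers were lower in 6 of 28 cases and higher in none (8 and 0 adjusted over the list alone, median -0.54, 0.000964, and adjusted p = 0.344 with an estimated correlation), a call lost without WT S1 (0.152, median 0.19). Endothelial and stromal markers were higher in 4 of 24 cases and lower in 1 (5 and 2 adjusted over the list alone, 0.0247, and adjusted p = 0.344 with an estimated correlation), a call lost without WT S2 (0.0506). Hox genes and cofactors were lower in 6 of 20 cases and higher in none (8 and 0 adjusted over the list alone, 5.12e-05, and adjusted p = 0.297 with an estimated correlation). Meis1 was at -0.86 ± 0.11 (0.000106). The collagen genes Col1a1 and Col1a2 were higher in WT_Prmt1 (6.53 ± 0.63, 0.00185 and 6.18 ± 0.51, 0.000585), and Klk1, with 0 counts in WT and 10.3 CPM in WT_Prmt1, was at least 139-fold higher. Dusp4, a MAP kinase phosphatase gene, was lower (57.1 and 5.69 CPM, -3.32 ± 0.17, 2.73e-09), as were Slco2a1 (-4.26 ± 0.56, 0.000174) and Gstm2 (-2.87 ± 0.41, 0.000330). In all, 633 genes were higher and 661 lower, so each knockout was compared only with the WT group of its own experiment. Higher calls were the majority in some settings, as with only the groups compared (1327 and 967), limma-voom (1159 and 877) and DESeq2 (1011 and 846). The total of 1294 became 641 without WT S1, 676 without WT S2, 663 without WT_Prmt1 S10 and 638 without WT_Prmt1 S11.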

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

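Of the tests below, the expected genomic DNA signal was the only one chosen beforehand, and all others were chosen after the result was seen. A difference between groups marked 2676 genes whose change differed between dKO and Prmt1_KO and 1439 genes that departed from additivity in dKO. The largest of the first kind were Dnase1l3 (7.80), Dynlt1b (7.75), Xcr1 (6.97), Fap (6.76) and Rps6ka6 (6.13) with the higher change in dKO, and Smoc2 (-7.59), Wfdc17 (-6.09), Ccl4 (-5.62), Pdcd1 (-5.36) and Ifnb1 (-5.24) with the lower. Dnase1l3 and Xcr1 were at 22.0 and 17.95 CPM in WT_Prmt1 but 3.22 and 2.87 in WT, which enters their values. Dnase1l3 lost its call without Prmt1_KO S9 (0.0501) and Smoc2 without WT S1 (1.00). The largest departures from additivity were those of Ltf (16.43), Mmp9 (14.13), Krt83 (11.11), Cntn1 (11.07) and Trim10 (11.01) above the sum, and of mt-Co2 (-5.63), mt-Atp6 (-5.42), Ddx3y (-4.60), Uty (-4.48) and Kdm5d (-4.46) below it. Ltf, Mmp9, Krt83, Cntn1 and Trim10 had 0 counts in Bcat_KO and Dynlt1b 0 counts in Prmt1_KO, and Smoc2 had few counts outside Prmt1_KO (0.0566 CPM in WT_Prmt1), so their fitted values and ranks depend on the prior count and are no bound. mt-Co2 and mt-Atp6 are uncertain, since reads shared with nuclear copies were not tested for. Ltf and Mmp9 lost their calls without either WT, Bcat_KO or dKO library (up to 0.131 and 0.115, without WT S1), and mt-Co2 in 5 of 8 fits (up to 0.174, without Hoxa9_KO S4).

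Lower mitosis and DNA replication genes in dKO could in part come from the sex or strain difference between WT and knockout cells. Between dKO and Hoxa9_KO, both male-typed, the mitosis median was -0.99 with 39 of 40 genes below 0 and the replication median -0.29 with 57 of 60, so that difference is excluded as the whole cause. Genomic DNA reads made up 0.122% of the fall for the median called gene of these lists and 1.43% at most, which excludes them.

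The Bcat_KO libraries stood apart from the other knockouts, at 82.0 and 85.9 on the first principal component, perhaps for a technical reason. Deeper sequencing is not excluded. A median of 17728 genes was detected in them, fewer than elsewhere. Yet they had the most genes with 10 counts or more (15205 and 15643), against 15122 at most elsewhere, in dKO S6. Detection at any count also takes in the receptor signal, which was higher in the other libraries, so it cannot decide. Genomic DNA reads could account for at least 50% of the fall in 4.92% of the genes lower in Bcat_KO (82 of 1665), so they do not account for most. Satellite-annotated features gave 11.9 CPM at most in Bcat_KO and 658 or more elsewhere, and a separate preparation cannot be told apart from genotype here.

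Pseudogenes separated WT from the other groups of its experiment. Gm9625 and Gm8730, 97.4% and 98.7% identical to Rplp0, were at 125 and 565 CPM in WT, and Rps3a3, 98.9% identical to Rps3a1, was at 410.2, 360.2 and 487 CPM in Hoxa9_KO, Bcat_KO and dKO. Reads shared with the parent gene might explain this, but the coefficient of variation of pseudogene plus parent was up to 0.982 times that of the parent alone, which leaves it open. Gm9625 and Gm8730 were also lower in WT_Prmt1 than in WT (-5.39 for the smaller of the differences), which is in line with a strain or colony difference of the WT mice and remains a hypothesis.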

How the results depend on the processing

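All added alternatives were chosen after the data were seen: counts halved to fragments, no X and Y genes, no Bcat_KO libraries, and protein-coding genes only. None of them moved a count of genes by over 1.5 times. Between dKO and Hoxa9_KO the count was 623 with no filter, 3 with only the groups compared (2 residual degrees of freedom), 157 with only the experiment and 621 with DESeq2. With only the groups compared it was 3041 between dKO and Bcat_KO, 955 for departure from additivity (955 with only the experiment too) and 2294 between the WT groups, where limma-voom gave 2036. Ctnnb1 in Bcat_KO lost its call with library-size scaling (-0.23) and with only the experiment (-0.25), as did Prmt1 in Hoxa9_KO with no filter (-0.26). With an estimated correlation 0 lists were called. At an unadjusted p under 0.05 the shared calls were 1313 for Hoxa9_KO and Bcat_KO, 2515 for Hoxa9_KO and dKO and 1585 for Bcat_KO and dKO. Fewer libraries or a looser threshold are part of several of these settings, and otherwise the cause was not tested.

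Leaving out 1 library gave 521 (without WT S1) to 948 genes (Hoxa9_KO S5) for Hoxa9_KO, 1312 (WT S2) to 2115 (Bcat_KO S3) for Bcat_KO, and 1698 (WT S2) to 2939 (dKO S6) for dKO. It gave 168 (Hoxa9_KO S5) to 607 (dKO S6) between dKO and Hoxa9_KO, 670 (WT S1) to 1388 (dKO S7) for departure from additivity, and 638 (WT_Prmt1 S11) to 676 (WT S2) between the WT groups. Ctnnb1 in Bcat_KO ranged from -0.36 (WT S1) to -0.22 (WT S2), Prmt1 in Hoxa9_KO from -0.30 (WT S1) to -0.23 (WT S2) and Prmt1 in dKO from -0.37 (dKO S7) to -0.30 (WT S2). The lone library left in a group is assumed to vary like the other groups. The counts for dKO against Bcat_KO (3237 to 3851), Prmt1_KO (3977 to 4136) and the difference between dKO and Prmt1_KO (1842 to 2735) did not move by over 1.5 times.

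The direction of the list test reversed for 5 lists when a library was left out, and the values below are their medians. Between dKO and Hoxa9_KO, oxidative phosphorylation went to -0.088 without dKO S6 and 0.093 without dKO S7, monocyte and dendritic cell markers to -0.17 without Hoxa9_KO S4, in a range of -0.21 (dKO S6) to 0.62 (Hoxa9_KO S5), and T and NK cell markers to -0.30 without dKO S6 and 0.80 without dKO S7. Between dKO and Bcat_KO, the B cell median stayed above 0 when the test reversed, at 0.30 without dKO S6 and 1.43 without Bcat_KO S4. Mitosis genes in the difference between dKO and Prmt1_KO went to 0.011 without dKO S7 and -0.60 without dKO S6. The cause was not tested. Of the other results for lists 6244 stayed the same, 388 were weaker and 191 stronger. No paired analysis was possible because the count columns carry S tags and not the replicate numbers of the labels. Depth was lowest in Hoxa9_KO S4, and genes with few counts were below the filter.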

Other observations

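Immunoglobulin transcripts varied between libraries of the same group. Ighm was at 24282 CPM in dKO S6 and 12111 in dKO S7, Igkc at 19098 and 7357, and Jchain at 4717 and 2234, against 2552 and 5845, 1324 and 2611, and 460.3 and 962 in WT. Ighg2c was at 11054 CPM in dKO S6 and 332 in dKO S7, and at 0.523 and 0.787 in WT. Immunoglobulin segments took 2.98% and 4.37% of the counts in Hoxa9_KO and 1.03% and 1.41% in Prmt1_KO. Of other plasma cell genes, Sdc1 was at 64.8 and 25.4 CPM in dKO against 41.4 and 39.0 in WT, Mzb1 at 20.9 and 8.01 against 10.1 and 13.97, and Xbp1 at 222 and 112 against 61.2 and 78.4. The B cell gene Cd79a was at 159 and 199.9 CPM in WT and at 50.9 and 15.2 in dKO.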
